A study of Arabidopsis thaliana with 6 samples.

How the data were processed

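RNA was measured in 6 libraries of Arabidopsis thaliana seeds, 3 of green and 3 of non-green (yellow) seeds, which segregate in the siliques of plants that carry a mutant allele of the chlorophyll synthase gene. Per the labels' protocols, plants grew at 22 °C with 16 h of light at 120 µE per square metre and second and 8 h of dark. Per the same protocols, seeds were taken out of the siliques, separated by colour and frozen, RNA was extracted with Trizol, and libraries were made from 1 µg of total RNA with an Illumina TruSeq kit. The age of the seeds is not given in the sources used here, nor are the number of plants behind a library and the nature of the mutation. Nothing in the labels says that the replicates came from separate plants or growths, so p-values measure only the spread between these samples, which may be technical.

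The authors deposited read counts per gene model for each library, with 32678 gene models in the table. Per the submitters' processing notes, Bowtie 0.12.2 and the genome build TAIR10 were used. The counting program, the gene models, the use of strand and the treatment of reads with several matches are not given in the sources used here. Bowtie of this version aligns without gaps, so reads that cross exon joins can be lost if they were aligned to the genome alone, which lowers the counts of genes with many short exons in both groups. Counts of near-identical gene copies (the LHCB1 genes, the 2S albumin genes SESA1 to SESA5, germin-like genes in tandem, small heat shock genes) can be split or exchanged between copies and are uncertain for single members. The authors also deposited RPKM values per library. From the 29216 values whose rounding moved the implied gene length by less than 0.05 bases, 100% gave a whole length within 0.05 bases, so RPKM is the same count scaled by gene length and library total, and it was used only for gene lengths. The authors' deposited table further holds a mean signal, a log2 fold change with its error, a test score and p-values of their own comparison, under column names that DESeq2 uses; the settings of that comparison are not given in the sources used here. In 22 rows the gene name had been turned into a date, and the symbol was taken from the RefSeq table of assembly TAIR10.1, which holds 97.7% of the gene identifiers.

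Total counts ran from 16438639 to 16745514 per library, and genes kept for testing held at least 99.9% of them. The counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were filtered with filterByExpr by group, which left 17239, library sizes were scaled with TMM factors (0.959 to 1.04), and non-green was compared with green by edgeR's quasi-likelihood test with group as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. The common biological coefficient of variation was 5.68%. CPM are counts per 1e6 counts after TMM scaling, with SD over the 3 libraries of a group. All tests were two-sided.

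Before the data were examined, 23 gene lists were fixed, covering chlorophyll synthesis, light-harvesting antenna, photosystem and electron transport, Calvin cycle, plastid-encoded genes, plastid fatty acid synthesis, oil assembly and oil bodies, seed storage protein, late embryogenesis abundant and desiccation genes, seed maturation and plastid regulators, sucrose, glycolysis and plastid transport, starch metabolism, carotenoid and ABA, oxidative stress, heat shock, hypoxia, sugar starvation, fatty acid breakdown and glyoxylate cycle, cell division and DNA replication, seed coat, endosperm, silique wall, and defense. The 21 lists with at least 5 tested members were tested with limma's camera on log2 CPM (prior count 2) with an inter-gene correlation of 0.01, adjusted over these lists. The rule for naming genes was fixed at the same time. It takes the chlorophyll synthase gene, then the 8 largest positive and the 8 largest negative fold changes among called genes whose groups do not overlap and whose mean lies in the upper part of the tested genes, above the median. From each list it takes up to 3 members with the smallest adjusted p and the first called member in the minority direction, and any member of the regulator list. Shares of the total count were compared by an exact permutation test, which cannot give a p under 0.1 with 3 libraries against 3.

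The test scripts were tested on simulated counts for the 17239 genes, with 200 genes changed among those with a mean count of at least 20. Recovery of genes below that count was therefore not tested. The scripts recovered 36% of genes changed 1.2-fold, 68% of those changed 1.5-fold, 98% at 2-fold and 100% at 4-fold, and 7 of 158 calls were false. Only 200 genes were changed there, while 4593 were called in the data. The Benjamini-Hochberg adjustment is stricter when fewer genes change, so these rates are not those of the real comparison. A planted list was found by camera, and 0 of the real lists were called in the simulation. Genes were drawn independently there, so this count says nothing about false calls of lists whose genes vary together. Libraries of a group differed by more than counting noise (chi-square per degree of freedom 2.46 to 3.05, genes with a summed count of at least 20), so none was a copy of another; between groups the value was 18.9 to 21.3.

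The alternatives tried were DESeq2 size factors in edgeR, TMM factors without the 20 most abundant genes, the Wald test of DESeq2 1.42.0, no filter on low counts, a robust prior, the replicate number as a block, leaving out each library in turn, camera with an estimated correlation, fry, and shares over nuclear genes. Under the Wald test, gene lists were tested by limma's cameraPR on its statistics in place of camera on log2 CPM. Scaling by total counts alone and enrichment over all called genes were added after seeing the data. Alternatives planned for a table of normalized values (other pseudocounts, value filters and scalings) were not run, since the table holds counts. Enrichment of GO terms, as annotated in the authors' deposited table, was tested by the hypergeometric test among genes called and changed at least 1.5-fold, per direction, over terms of 10 to 500 of the tested genes.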

Results

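Transcript levels were measured by RNA sequencing in seeds of an Arabidopsis line that segregates for a mutation in chlorophyll synthase, the enzyme that attaches the phytol tail in the last step of chlorophyll synthesis. Green seeds, which can photosynthesise and are labelled as carrying a wild-type allele, were set against yellow, non-green seeds, which per the design text cannot, although their sample titles also hold the word photosynthetic, and which are labelled with the mutant allele alone. Both kinds lie side by side in the same siliques, and the series concerns the part that photosynthesis of the seed itself plays in oil accumulation. There were 3 libraries per group, with total counts of 16438639 to 16745514.

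The chlorophyll synthase gene (CHLG, AT3G51820) was lower in non-green seeds, with 46, 50 and 65 counts in the green libraries and 11, 6 and 9 in the non-green ones. This is a log2 fold change of -2.69 ± 0.36 (SE, n = 3 per group, edgeR adjusted p = 1.32e-09), from 3.32 ± 0.588 (SD) to 0.507 ± 0.144 CPM. The gene lies on chromosome 3 at 19215930 to 19219128 in TAIR10.1, on the minus strand, with 14 annotated exons. The genes with the locus numbers on either side of it were not called. EM1 (AT3G51810) had a log2 fold change of 0.02 ± 0.03 (edgeR adjusted p = 0.799) and SAC8 (AT3G51830) of -0.22 ± 0.13 (edgeR adjusted p = 0.214).

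Beyond it, non-green seeds held more transcript of genes that make fatty acids in the plastid (29 of 34 higher, median log2 fold change 0.44, n = 3 per group), of starch genes (10 of 14, median 0.55) and of heat shock genes (6 of 7, median 1.06). They held less of photosystem genes (22 of 34 lower, median -0.27) and of antenna genes (13 of 19 lower, median -0.24). Of these 5 lists, fatty acid synthesis alone kept its call with an estimated correlation between genes (adjusted p = 0.0159, against 0.0534 for starch and heat shock and 0.121 for photosystem and antenna).

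ELIP1, an early light-induced protein of the thylakoid, had the largest rise among called genes above the median expression whose groups do not overlap, from 8.26 ± 1.2 to 142 ± 8.16 CPM (SD, n = 3), or 17.1-fold, a log2 fold change of 4.1 ± 0.07 (SE). The plastid glucose 6-phosphate translocator gene GPT2 rose by 3.24 ± 0.04, from 58.5 ± 2.82 to 552 ± 3.46 CPM. The related genes EXO and PHI-1, annotated as phosphate-responsive, rose by 3.35 ± 0.10 and 2.32 ± 0.07. CYP707A3, which encodes an abscisic acid hydroxylase, rose by 2.74 ± 0.13, the transcription factor gene WRKY33 by 2.23 ± 0.14, the embryo-specific protein gene AT5G62210 by 2.40 ± 0.13 and the tetratricopeptide repeat gene AT2G29670 by 2.21 ± 0.12. The falls were smaller. The cell wall gene EXT3 had a log2 fold change of -1.42 ± 0.07, the MADS-box gene SEP3 -1.38 ± 0.13, the pectin lyase-like gene AT2G43880 -1.02 ± 0.08 and AT1G62240, which has no description in the table, -1.0 ± 0.05. The germin-like or cupin genes AT3G04170, GER2, AT3G04180 and AT3G04150 had -1.08 ± 0.03, -1.03 ± 0.07, -1.02 ± 0.05 and -1.0 ± 0.05; AT3G04170 went from 1433 ± 33.3 to 678 ± 9.87 CPM. Reads of these tandem germin-like copies can be exchanged between them.

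Of 17239 genes tested, 4593 (26.6%) passed edgeR's adjusted threshold, 2444 higher and 2149 lower in non-green seeds. Most changes were small, with a median absolute log2 fold change of 0.41 among called genes. At 1.5-fold or more, 947 genes were higher and 454 lower, and at 2-fold or more 414 and 98. Higher genes made up 53.2% of calls; with scaling by total counts alone, chosen after seeing the data, they made up 70.5%, with 3266 higher and 1364 lower. In the values that the authors deposited, 4091 genes pass an adjusted p of 0.05, 2176 higher and 1915 lower. Of these, 4043 genes were called in both, 100% of them with the same sign. Chlorophyll synthase is listed there at -1.70, while all alternatives tried here gave -2.89 to -2.49. The settings behind the deposited value are not given in the sources used here, so the 2 estimates may not be the same measure.

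**Figure D1:**
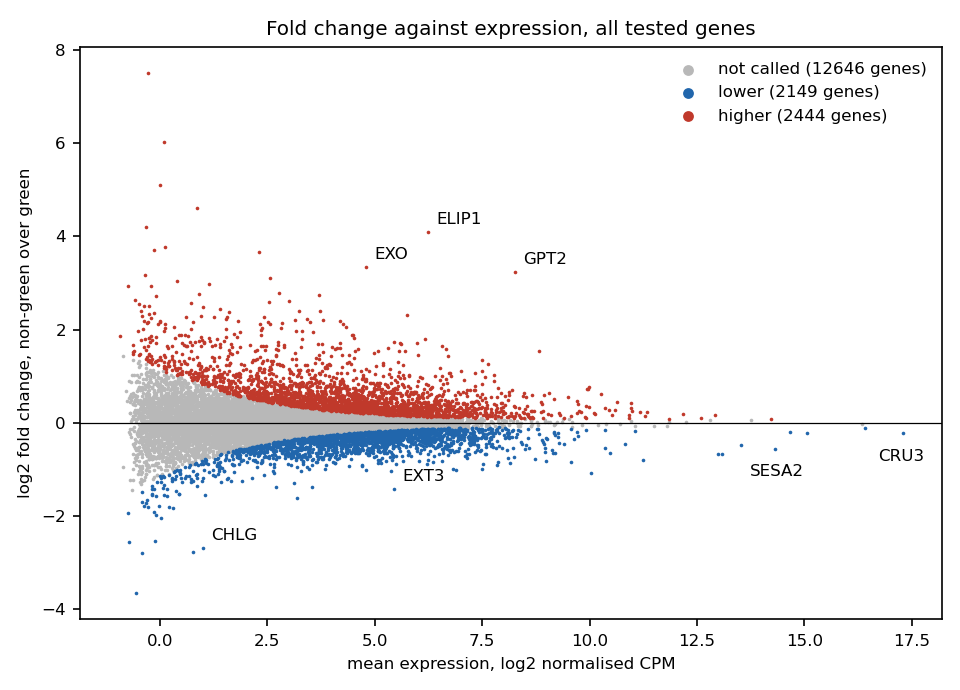
Log2 fold change of non-green over green seeds (y axis) against mean expression in log2 normalised CPM (x axis) for the 17239 tested genes. Red points are the 2444 genes called higher, blue points the 2149 called lower and grey points the rest; ELIP1 lies at 4.1, GPT2 at 3.24 and CHLG at -2.69.

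Genes of plastid fatty acid synthesis, which make the acyl chains of seed oil, rose together. Of 34 measured members 29 were higher, 1 was lower and 4 did not pass, with a median log2 fold change of 0.44 (camera adjusted p = 2.10e-14, and adjusted p = 0.0159 with an estimated correlation). The acyl carrier protein gene ACP2 rose from 93.4 ± 3.13 to 176 ± 9.44 CPM (0.91 ± 0.04), and the stearoyl-ACP desaturase genes AAD1 and FAB2 rose by 0.98 ± 0.05 and 0.63 ± 0.04. The exception was the acyl-ACP thioesterase gene FATB, at -0.24 ± 0.05 (edgeR adjusted p = 1.43e-05). For this and the other lists, counts adjusted over the list alone were the same as those over all genes except where given. In the same libraries 5 of 13 seed coat markers were lower and 2 higher, and the share of each tissue was not measured.

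Genes of oil assembly and oil bodies went both ways. Among 26 members 12 were higher and 3 lower (14 and 4 adjusted over the list alone). The desaturase gene FAD3 rose by 0.73 ± 0.03, from 754 ± 22.0 to 1248 ± 4.65 CPM, the oleosin gene OLEO3 by 0.72 ± 0.03 and the fatty acid elongase gene FAE1 by 0.59 ± 0.04, while the aminoalcoholphosphotransferase gene AAPT2 was at -0.57 ± 0.05. The list was called higher (camera adjusted p = 0.0165), but not with an estimated correlation (adjusted p = 0.247) and not without green replicate 1 (adjusted p = 0.0709).

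Among 17 measured regulators of seed maturation and plastids, 6 were higher and 2 lower, and the list as a whole was not called (camera adjusted p = 0.143). WRI1, an activator of glycolytic and fatty acid synthesis genes, rose from 59.3 ± 0.481 to 99.1 ± 2.34 CPM (0.74 ± 0.05), and L1L, a LEC1-like factor, from 26.0 ± 1.09 to 54.0 ± 0.921 CPM (1.05 ± 0.07). EEL, ABI5 and FUS3 rose by 0.34 ± 0.04, 0.45 ± 0.06 and 0.29 ± 0.05, and BZIP25 was at -0.47 ± 0.08. BZIP67 (-0.16 ± 0.04) lost its call without green replicate 2 (adjusted p = 0.0588) and with scaling by total counts (-0.08, adjusted p = 0.189). DOG1 (0.11 ± 0.04) lost its call without either of green replicates 2 (0.153) and 3 (0.102) and of non-green replicates 1 (0.0957) and 2 (0.157), with DESeq2 (0.0648) and with no filter on low counts (0.0512). ABI3, at 0.04 ± 0.04 (adjusted p = 0.431; called at 0.12 with scaling by total counts, adjusted p = 0.00842), and the chloroplast regulator GLK2, at -0.12 ± 0.13 (adjusted p = 0.576), did not pass.

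Starch genes rose, with 10 of 14 higher (11 adjusted over the list alone) and 0 lower, and a median of 0.55. The list had a camera adjusted p of 7.08e-06, and an adjusted p = 0.0534 with an estimated correlation. The starch synthase gene GBSS1 rose from 17.2 ± 2.05 to 49.6 ± 2.29 CPM (1.53 ± 0.08), the branching enzyme gene SBE2.2 by 0.93 ± 0.08 and ADG1, a subunit gene of ADP-glucose pyrophosphorylase, by 0.74 ± 0.05. For sucrose use, glycolysis and plastid transport, 12 of 28 genes were higher and 5 lower. Besides GPT2, the plastid enolase gene ENO1 rose by 1.03 ± 0.06 and the plastid pyruvate kinase gene PKPB1 by 0.65 ± 0.04, whereas the sucrose exporter gene SWEET11 was at -0.54 ± 0.04. This list stayed just outside the threshold (camera adjusted p = 0.0541). It was called without green replicate 2 (0.0448) or non-green replicate 3 (0.0434) and with no filter on low counts (0.0325). With DESeq2, where cameraPR on the Wald statistics replaced camera, it was called too (9.49e-13).

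Nuclear genes of the photosynthetic membrane moved the other way. Of 34 photosystem and electron transport genes 22 were lower (23 adjusted over the list alone) and 2 higher, with a median of -0.27 (camera adjusted p = 1.18e-05, and adjusted p = 0.121 with an estimated correlation). The photosystem I gene PSAF went from 49.9 ± 0.669 to 35.2 ± 1.21 CPM (-0.50 ± 0.06), and the photosystem II gene PSBQ2 had -0.36 ± 0.05, while the ferredoxin gene FD1 rose by 0.75 ± 0.10. Among 19 antenna genes 13 were lower and 2 higher, with a median of -0.24 (camera adjusted p = 0.000878, and adjusted p = 0.121 with an estimated correlation). LHCA1 fell from 76.0 ± 1.25 to 49.8 ± 0.356 CPM (-0.61 ± 0.05) and LHCB1.3 had -0.37 ± 0.04, although near-identical LHCB1 copies make its own value uncertain. LHCB4.3 rose by 0.64 ± 0.06. In the same libraries the seed coat marker TT10 was at -0.44 ± 0.04.

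The lists of other chloroplast functions were not called. Of 28 chlorophyll synthesis genes 3 were higher and 2 lower (camera adjusted p = 0.520); PORB, a protochlorophyllide reductase gene, went from 14.2 ± 2.03 to 7.33 ± 0.692 CPM (-0.95 ± 0.13), and CHLH, for a magnesium chelatase subunit, and FC1, a ferrochelatase gene of the haem branch, rose by 0.35 ± 0.07 and 0.35 ± 0.08. Of 18 Calvin cycle genes 9 were higher and 3 lower (camera adjusted p = 0.157), with GAPB at 0.42 ± 0.05, FBA2 at 0.42 ± 0.07, PRK at 0.38 ± 0.06 and CP12-1 at -0.32 ± 0.06. Of 22 plastid-encoded genes in the list 14 had enough counts to test, of which 1 was higher and 1 lower. The list was not called (camera adjusted p = 0.986, with a median of 0.06 and a test direction that was negative). With so few counts this says little about plastid transcripts. ATPB had -0.88 ± 0.22, and PSAB, at 0.32 ± 0.11, lost its call without green replicate 1 (0.0921) or 2 (0.180), without non-green replicate 1 (0.0633) or 2 (0.307) and with DESeq2 (0.109).

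**Figure D2:**
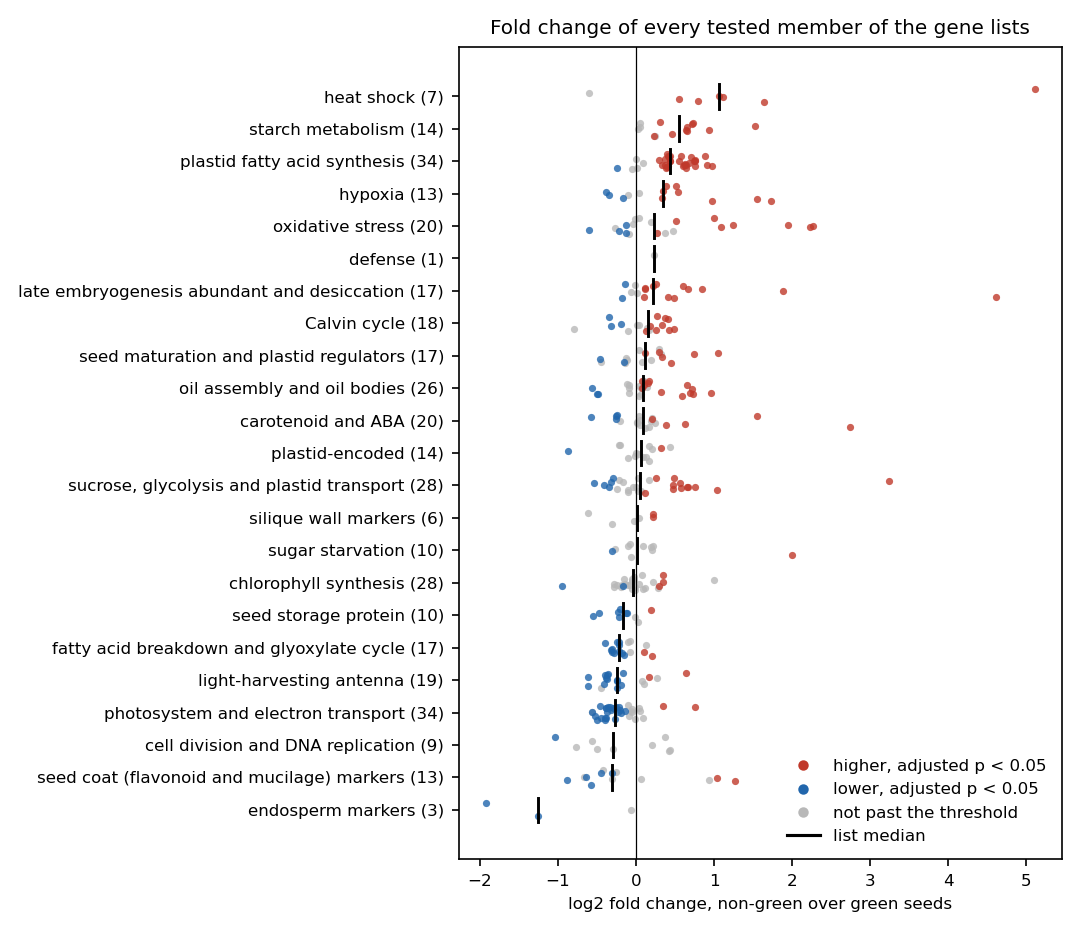
Log2 fold change of non-green over green seeds (x axis) for every tested member of the 23 gene lists (y axis, tested members in brackets). Red and blue points are members called higher and lower at an edgeR adjusted p under 0.05, grey points did not pass, and black bars are list medians, at 0.44 for plastid fatty acid synthesis and -0.27 for photosystem genes.

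Seed storage protein genes were lower in 7 of 10 cases and higher in 1, with a median of -0.16 (camera adjusted p = 0.0165, and adjusted p = 0.360 with an estimated correlation). Under scaling by total counts they were lower in 6 and higher in 3, with a median of -0.09. The albumin genes SESA2 and SESA1 had -0.55 ± 0.03 and -0.48 ± 0.03, the cruciferin gene CRU3 -0.23 ± 0.02 and the vicilin-like gene PAP85 0.19 ± 0.03. Together these 10 genes took 44.9% ± 0.437 of all counts in green and 41.8% ± 0.361 in non-green libraries (SD, n = 3; exact permutation p = 0.1, the smallest that 3 against 3 allows). CRU3 alone took 16.9% ± 0.132 and 15.2% ± 0.200, and the 20 most abundant genes 53.3% ± 0.508 and 50.2% ± 0.456 (exact permutation p = 0.1). Nuclear photosynthesis genes took 0.460% ± 0.00163 and 0.442% ± 0.00392 (exact permutation p = 0.1), and plastid-encoded genes 0.0425% ± 0.00272 and 0.0472% ± 0.00716 (exact permutation p = 0.4). How completely the libraries captured plastid RNA was not measured, so the plastid-encoded shares do not give the abundance of plastid transcripts in the seed.

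Late embryogenesis abundant genes, which act in drying seeds, were higher in 12 of 17 cases and lower in 2, with a median of 0.21 (camera adjusted p = 0.000480, and adjusted p = 0.275 with an estimated correlation). M10 rose from 9.32 ± 1.16 to 34.6 ± 1.63 CPM (1.89 ± 0.10), EM6 by 0.84 ± 0.05 and LEA25 by 0.60 ± 0.04, and LEA76 was at -0.18 ± 0.03. Fatty acid breakdown and glyoxylate cycle genes were lower in 11 of 17 cases (12 adjusted over the list alone) and higher in 2, with a median of -0.21 (camera adjusted p = 0.00233, and adjusted p = 0.121 with an estimated correlation). Under scaling by total counts they were lower in 7, with a median of -0.14. The acyl-CoA oxidase gene ACX1 had -0.40 ± 0.05, the citrate synthase gene CSY3 -0.31 ± 0.05 and the isocitrate lyase gene ICL 0.20 ± 0.03.

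Heat shock genes rose in 6 of 7 measured cases, with 0 lower and a median of 1.06 (camera adjusted p = 9.52e-06, and adjusted p = 0.0534 with an estimated correlation). HSP17.6A rose from 45.9 ± 4.25 to 144 ± 8.49 CPM (1.65 ± 0.05), HSP17.4 by 1.12 ± 0.04 and HSP90.1 by 1.06 ± 0.04. The oxidative stress list was called higher (camera adjusted p = 0.0165, and adjusted p = 0.168 with an estimated correlation), with 8 of 20 genes higher and 4 lower (5 adjusted over the list alone, 2 under scaling by total counts). The zinc finger genes ZAT12 and ZAT10 rose by 1.09 ± 0.06 and 1.00 ± 0.05, and the catalase gene CAT1 was at -0.21 ± 0.04. In the hypoxia list 8 of 13 genes were higher and 3 lower (camera adjusted p = 0.0119, and adjusted p = 0.121 with an estimated correlation). SAD6, a desaturase gene, rose from 231 ± 4.75 to 676 ± 10.6 CPM (1.55 ± 0.04), the haemoglobin gene HB1 by 1.73 ± 0.17 and the alcohol dehydrogenase gene ADH1 by 0.51 ± 0.04, and LBD41 was at -0.38 ± 0.04. For carotenoids and abscisic acid, 5 of 20 genes were higher and 4 lower, and the list was not called (camera adjusted p = 0.143). CYP707A1, like CYP707A3 a gene of abscisic acid breakdown, rose by 1.55 ± 0.09, the synthesis gene NCED9 rose by 0.63 ± 0.09, and the synthesis gene AAO3 was at -0.57 ± 0.10.

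**Figure D3:**
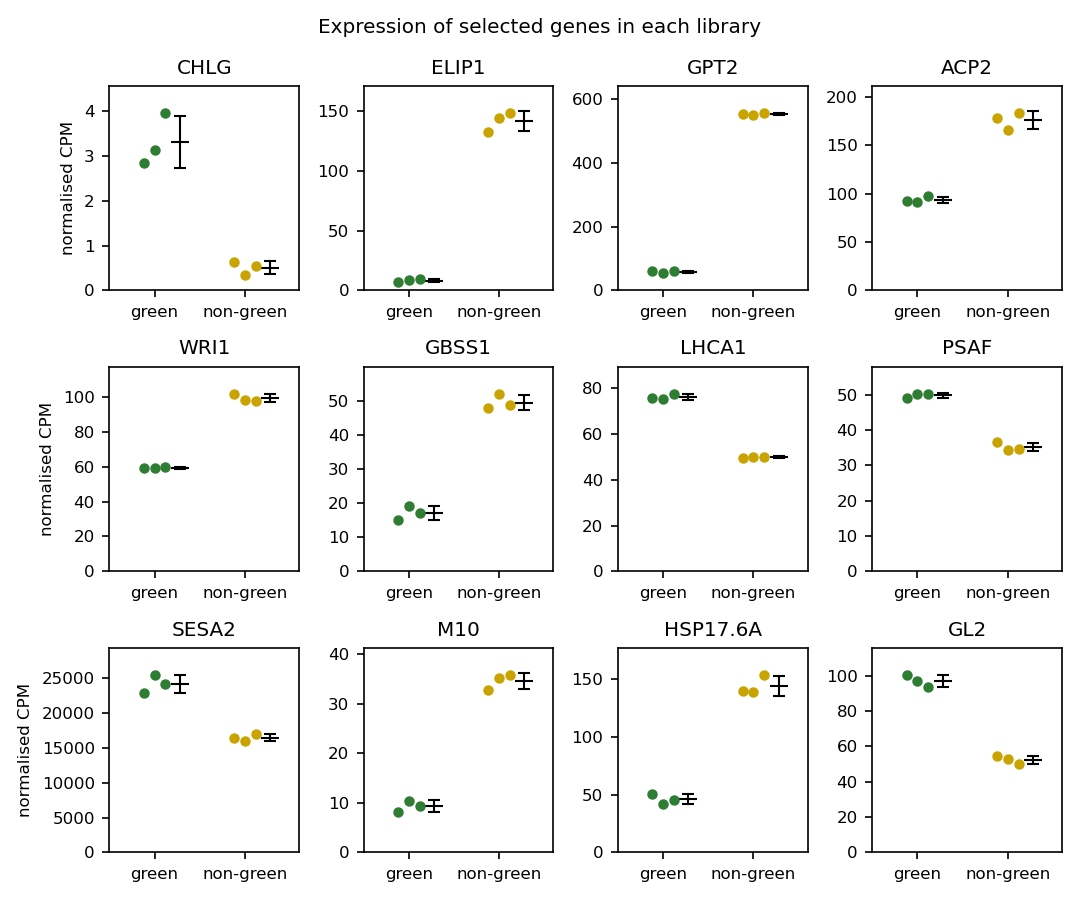
Normalised CPM (y axis, linear from 0, a scale of its own per panel) of 12 named genes in the 3 green and 3 non-green libraries. Dots are libraries, and the bar beside them is the mean with its SD; GPT2 stands at 58.5 in green and 552 in non-green seeds, and LHCA1 at 76.0 and 49.8.

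Markers of other tissues in the seed or silique were measured in the same libraries. Of 13 seed coat genes 5 were lower and 2 higher, and the list was not called (camera adjusted p = 0.121). The mucilage regulator gene GL2 went from 97.1 ± 3.41 to 52.4 ± 2.34 CPM (-0.89 ± 0.05) and the laccase gene TT10 from 725 ± 25.1 to 532 ± 5.15 CPM, whereas the chalcone synthase gene CHS rose by 1.27 ± 0.04. Only 3 endosperm markers had enough counts, of which MEA (-1.26 ± 0.23) and ALE1 (-1.92 ± 0.49) were lower. Of 6 silique wall markers 2 were higher and 0 lower (1 lower adjusted over the list alone), without a call for the list (camera adjusted p = 0.972; median 0.01, mean -0.07). FIL (0.22 ± 0.07) lost its call without non-green replicate 1 (0.0622) or 3 (0.226), and YAB3 (0.22 ± 0.08) without green replicate 1 (0.286), non-green replicate 2 (0.0834) or 3 (0.118); with DESeq2 neither passed (0.0688 and 0.101). SHP1 did not pass (-0.30 ± 0.12, adjusted p = 0.0583), but was called lower with the replicate block (-0.31, adjusted p = 0.0428) and without green replicate 1 (-0.39, 0.0300) or non-green replicate 3 (-0.49, 0.00303).

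The lists of cell division (0 higher and 1 lower of 9, camera adjusted p = 0.595) and sugar starvation (1 higher and 1 lower of 10, camera adjusted p = 0.972) were not called. The topoisomerase gene TOP2 had -1.04 ± 0.35 and lost its call without green replicate 3 (0.0619) or non-green replicate 2 (0.0506) or 3 (0.104). SEN1 had 2.01 ± 0.55, which lost its call without non-green replicate 3 (0.0504), and TPS8 had -0.31 ± 0.07. Of the defense list 1 gene was measured, AOS, at 0.22 ± 0.09 (edgeR adjusted p = 0.0569, and called when adjusted over the list alone or with scaling by total counts, adjusted p = 0.00965).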

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

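Scaling by total counts and enrichment over all called genes were chosen after seeing the data; the other alternatives were planned. Over all alternatives, called genes numbered 3673 (DESeq2) to 4643, and without single libraries 3968 to 4150. Scaling by total counts moved genes lower to 1364 and those at least 1.5-fold lower to 288 from 454, and called the seed coat list (adjusted p = 0.0459); it raises the non-green libraries relative to TMM, and the median log2 fold change of all tested genes from 0.00 to 0.08. The chlorophyll synthase log2 fold change stayed between -2.89 and -2.49. Of 103 other named genes, 89 stayed on their side of the threshold in each of 13 alternatives, and 0 reversed. Camera called 11 lists; with an estimated correlation it called 1, plastid fatty acid synthesis. Adjusted p was then 0.121 for antenna, photosystem, hypoxia and fatty acid breakdown, 0.0534 for starch and heat shock, 0.168 for oxidative stress, 0.247 for oil assembly, 0.275 for late embryogenesis and 0.360 for storage protein; this setting allows for genes that vary together. fry, which asks whether a list moves and not whether it moves more than others, called 17, adding Calvin cycle (0.000642), regulators (0.00149), sucrose and glycolysis (1.69e-05), carotenoid and ABA (0.000241), cell division (0.0218) and seed coat (0.0292). With DESeq2 the lists were tested by cameraPR on its Wald statistics, not by camera on log2 CPM. That test called regulators (0.00828) and sucrose and glycolysis (9.49e-13), and these values are not those of the same list test under another fit. With no filter on low counts camera called sucrose and glycolysis (0.0325). The causes were not tested. Without single libraries oil assembly ranged from 0.0170 to 0.0709 and sucrose and glycolysis from 0.0434 to 0.105; the cause was not tested. The robust prior does not enter camera. The replicate block gave 4643 calls and 11 lists; deviations of same-numbered libraries correlated at 0.0133, 0.00385 and -0.00140, so the numbers pair nothing, and not every library correlated best with its own number. The differences in shares of counts moved by less than their pooled within-group SD; that of plastid-encoded genes ranged from 0.00130 to 0.00844 percentage points without single libraries. At this depth genes with few counts, as most endosperm markers, could not be tested.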

Other observations

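The enrichment tests, and the tests of scaling, seed age, seed coat share and neighbouring genes below, were chosen after the results were seen, as were the genes named here. Among genes at least 1.5-fold higher in non-green seeds, GO terms of stress responses and of xyloglucan metabolism were among those enriched. Seeds were separated by colour before they were frozen, and whether handling differed between the colours was not tested. Of 93 tested genes annotated to the response to chitin, 37 were in this set (hypergeometric adjusted p = 9.30e-20), with the zinc finger gene SZF1 at a log2 fold change of 1.79 ± 0.06 (SE, n = 3 per group) and the redox-responsive factor gene RRTF1 at 1.61 ± 0.10. The response to karrikin came next (34 of 117, adjusted p = 2.14e-13). The response to wounding (23 of 160, adjusted p = 0.00199), heat (27 of 135, adjusted p = 8.96e-07), hydrogen peroxide (13 of 51, adjusted p = 0.000262) and high light (12 of 56, adjusted p = 0.00298) were enriched too. Xyloglucan metabolism, a part of cell wall remodelling, had 12 of 23 genes in the set (adjusted p = 2.20e-07), with XTH16 at 2.06 ± 0.10, TCH4 at 1.55 ± 0.06 and XTH25 at 0.61 ± 0.03 reaching 1487 ± 56.5 CPM (SD) in non-green seeds. ELIP2, the relative of ELIP1, was at 1.83 ± 0.09, and the flavonol synthase gene FLS1 at 1.72 ± 0.06.

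Among genes at least 1.5-fold lower, 8 GO terms were enriched, 18 without non-green replicate 3, 5 with scaling by total counts and 75 over all called genes. Manganese ion binding, which holds the germin-like genes, had 9 of 27 genes in the set (adjusted p = 1.38e-05) and 0.0583 as its adjusted p over all called genes. Wall terms were enriched in both directions: apoplast had 28 of 313 genes in the lower set (adjusted p = 1.38e-05) and 36 in the higher (adjusted p = 0.00199), and cell wall 22 of 361 (adjusted p = 0.0428) and 45 (adjusted p = 2.91e-05). Cell wall lost its call among lower genes without green replicate 1 (0.0733) or 2 (0.0535) or non-green replicate 1 (0.142), with the replicate block (0.0829) and with scaling by total counts (0.425). Cell wall organization (14 of 173 lower, adjusted p = 0.0384) lost its call on leaving out each library in turn (0.0597 to 0.593). Seed coat development had 8 of 24 (adjusted p = 4.78e-05). Suberin synthesis had 4 of 12 (adjusted p = 0.0384), which was lost without green replicate 2 (0.203) or non-green replicate 2 (0.213) and with scaling by total counts (0.499). Over all fold sizes 10 genes annotated to suberin synthesis were called lower, among them RWP1 at -0.61 ± 0.04 and CYP86B1 at -0.45 ± 0.04.

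The rise of fatty acid synthesis genes beside the fall of antenna and photosystem genes was set against 4 explanations. The values argue against expression level and gene length as the source, as 3 of the 3 list medians (0.44, -0.24 and -0.27) lay outside the central 99% of 10000 random lists matched on both. Random lists treat genes as independent, and antenna and photosystem genes lost their call with an estimated correlation (camera adjusted p = 0.121 for each). The values also argue against the choice among 4 scalings as the source, as under each of them 3 of the 3 lists kept their direction. Fatty acid synthesis had 29 higher and 1 lower. Under total counts antenna had 12 lower and 3 higher, and photosystem genes 18 lower and 3 higher. These scalings shift all genes alike and moved the medians little (antenna to -0.17 under total counts), so an error of scaling that they share was not tested. Seed age stays open: against younger non-green seeds 12 late embryogenesis genes rose and 2 fell (adjusted p = 0.275 for the list with an estimated correlation), but 7 storage protein genes fell and 1 rose (0.360; 6 and 3 under total counts), and their share of counts went from 44.9% to 41.8%, while for older seeds the 29 risen fatty acid genes are the pattern itself, and L1L (1.05 ± 0.07) and WRI1 (0.74 ± 0.05), which should be lower, were higher, but 2 genes do not decide it. Both kinds lie in the same siliques, which limits a difference in seed age, but neither the age nor the pace of development was measured. A changed mix of tissues was not tested for this pattern and stays open, as the share of each tissue was not measured. In the same libraries 17 of 24 seed coat development genes were lower and 1 was higher. The genotype of the seed and the loss of its chlorophyll stay open too and cannot be separated in this design.

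The fall of seed coat development genes may come from a smaller share of seed coat tissue in the non-green libraries. Of 24 tested genes 17 were lower, 1 (4.17%) was higher and 91.7% had a negative log2 fold change, with a median of -0.47. CESA9 at 0.29 ± 0.08 moved against a change of tissue share alone. The 2 higher members of the planned seed coat list were CHS at 1.27 ± 0.04 and CHI at 1.04 ± 0.13. Whether these 2 genes are transcribed in the coat alone was not measured, so their rise decides nothing about the share. As a whole the planned list leaned lower, with 5 of 13 lower and a median of -0.31. Its camera adjusted p was 0.121, and 0.253 with an estimated correlation, and its fry adjusted p was 0.0292. Its missing camera call therefore does not count against a smaller share. CHS and CHI also belong to flavonoid synthesis, which is therefore not separate evidence. That term was enriched among higher genes (7 of 30, hypergeometric adjusted p = 0.0322, but 0.0878 with scaling by total counts and 0.404 over all called genes). STK (-0.58 ± 0.05), DELTA-VPE (-0.70 ± 0.05) and AT1G62080 (-0.66 ± 0.03) moved as a smaller share predicts. A smaller share cannot be told apart from altered expression within the coat, which is tissue of the mother plant, because no value gives the amount of coat RNA in a library. Chance choice of genes is argued against by the enrichment, which is adjusted over the 1191 terms searched (4.78e-05, at most 0.000680 over the alternatives) and treats genes as independent; the median, at percentile 0 of 10000 random lists matched on expression, adds nothing, as the term was picked for being enriched.

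A segment of chromosome 3 carried along with the mutation could change genes near chlorophyll synthase. Among its 60 nearest tested neighbours 21.7% (13 genes) were called, below the 26.7% of the median window over the nuclear genome, and the upper bound set from the windows was 40%. The largest absolute log2 fold change among these neighbours was 0.88. These values argue against a dense cluster of called genes among the 60 neighbours. The share counts calls alone, so a segment that changed only a few of these genes, or genes further away, would not be seen.

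The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split (1 of 10) called 4593 genes with edgeR, 2444 higher and 2149 lower, and 11 lists. The highest count in any other split was 0 genes in total and per direction, and 2 lists. At an unadjusted p under 0.05 edgeR gave 307 to 365 genes there, against 6066 in the real split. Each other split mixes green and non-green libraries, so the difference between the colours enters its spread within groups and lowers its calls. The counts of those splits are therefore not the counts expected without a difference between the colours.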
